A study of Homo sapiens with 4 samples.

How the data were processed

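RNA was measured in 4 libraries of HCT116 cells, an established human colorectal carcinoma line carrying a doxycycline-inducible short hairpin RNA (shRNA) against UBA2. UBA2, also called SAE2, is the catalytic subunit of the E1 enzyme that activates the small modifier SUMO. Per the labels, 2 cell lines were made with 2 independent shRNAs, doxycycline was given for 3 days, total RNA including small RNA was extracted, ribosomal RNA was removed with a Ribo-Zero Gold kit and stranded libraries were made with a KAPA kit. Each line gave 1 library marked minus and 1 marked plus, read here as without and with induction.

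The deposited table holds RPKM values (reads scaled by gene length and by library size) for 10797 gene symbols, with 1 column per library. Per the submitters' processing notes, TopHat2 2.0.8b and edgeR were among the tools and hg19 (GRCh37) was the genome build. The gene annotation, the counting tool and the strand setting of the counting are not given in the sources used here. The smallest row maximum in the deposited RPKM table was 3.00 and the smallest row mean was 1.38, so genes of low level are not analysed here and a gene absent from the table was not called unexpressed. The sequencing depth is unknown, since RPKM values carry no counts. No interval or detection floor was therefore computed. The reference used here is of another build than the deposited values, so no coordinates are given.

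Columns were matched to libraries by the library number shared by column name and sample title. For replicate 2 the column names write sh4 where the titles write sh2. The plus library of replicate 1 carries no shRNA number in its label and was taken as the remaining library of line 1 by elimination, so the values given per line for line 1 rest on that reading. The comparison of plus with minus does not. The labels do not say whether the libraries came from more than 1 culture per line and condition, so p-values measure the spread between these libraries. An unnamed column with text in 2 rows was not used. The result of 1 gene is not reported here.

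Values were analysed as log2(RPKM + 1), and every fold change is on that scale, which understates the change of genes at low level. The 2 plus libraries were compared with the 2 minus libraries in limma 3.58.1 (R 4.3.3) with an intensity-dependent prior variance, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A minimum mean RPKM of 1 was set but removed no gene. The tests, 30 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is said to be later. List members were matched by symbol or by an older symbol in the RefSeq gene table (GRCh38.p14). Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera asks whether a list moved relative to the other genes, and fry asks whether its members moved, on balance, one way.

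Matches to the seed sites of miR-34a/c (CACTGCC) and miR-34b (ACTGCCT), positions 2 to 8 of the microRNA, were searched in the longest annotated 3' UTR of each gene in GENCODE 29. A 3' UTR was found for 9709 genes, 89.9% of the table, and 100 shuffles of each site served as control sites. Python 3.11.15 was used for these steps.

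The genes named by the rule are UBA2, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold that moved the same way in both lines, up to 4 members of each list with the largest absolute moderated t, and MYC. Small RNA genes, antisense genes and unnamed loci were left out of the 12 and 12. The same-numbered libraries were taken to come from the same cell line, which for replicate 1 rests on the elimination described above. The correlation across genes between the line difference without induction and that with induction was 0.103, over 2 pairs. A fit with the line as a block was run as an alternative.

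The limma steps were tested on simulated data for the comparison of plus with minus, with 10797 genes of which 200 were changed. At a log2 change of 1 or -1, 73.0% of the changed genes were recovered, and at 0.3 or -0.3 none were (0%). Of the calls, 1.35% were false. The simulation shuffled the spread among genes and changed only 200 genes, whereas limma called 46.2% of the genes in the real comparison. These rates therefore do not carry over to the real comparison. Alternatives tried were pseudocounts of 0.1 and 5, mean RPKM minimums of 0.1 and 5 and none, median-of-ratios scaling, quantile normalization, no variance trend, the line as a block, leaving out small RNA genes, leaving out each library in turn, and fold thresholds of 1.5 and 3 for the comparison between lines.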

Results

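Gene expression was measured by total RNA sequencing in HCT116 cells with (n = 2) and without (n = 2) induction of an shRNA against UBA2, in 2 cell lines with independent shRNAs. The induced library of line 1 was assigned by elimination. The deposited values cover 10797 genes in RPKM, with a median of 13.3 and 12.8 RPKM in the uninduced libraries and 12.2 and 12.3 RPKM in the induced libraries. The read depth behind these values is unknown.

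UBA2, the target of the shRNAs, fell in both lines. Its level went from 33.7 to 8.16 RPKM in line 1, leaving 24.2%, and from 37.6 to 10.1 RPKM in line 2, leaving 26.9%. The group means were 35.6 ± 2.76 RPKM without and 9.15 ± 1.39 RPKM with induction (SD, n = 2), a log2 change of -1.86 ± 0.10 (SE, limma adjusted p = 3.1e-05).

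**Figure D1:**
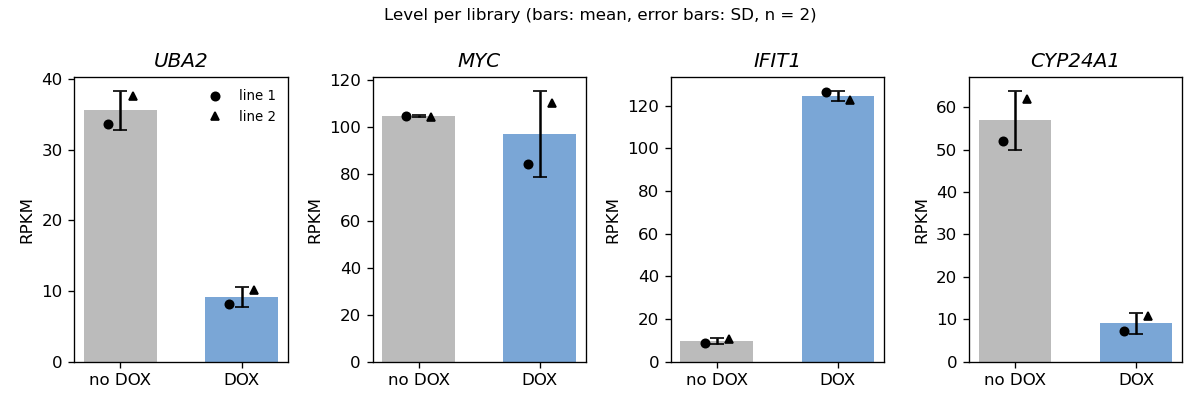
RPKM of UBA2, MYC, IFIT1 and CYP24A1 without and with doxycycline (DOX). Bars are group means, error bars the SD (n = 2), circles line 1 and triangles line 2. UBA2 stood at 35.6 RPKM without and 9.15 RPKM with induction, whereas the induced MYC libraries lay on either side of the uninduced ones.

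The design asks which genes change when the SUMO E1 enzyme is depleted. The libraries analysed here include none with doxycycline and no shRNA, or with a non-targeting shRNA. For all changes given below, UBA2 loss therefore cannot be told apart from a response to doxycycline or to any induced shRNA. Interferon-stimulated genes made up 7 of the 12 genes with the largest rise. SPTSSB, a small subunit of serine palmitoyltransferase, rose from 1.34 ± 0.44 to 93.4 ± 7.59 RPKM (SD, n = 2). The chemokine gene CCL26 rose from 3.05 ± 1.33 to 87.4 ± 13.0 RPKM. IFI6 rose from 46.9 ± 11.2 to 831 ± 73.8 RPKM and IFI27 from 16.0 ± 4.15 to 221 ± 63.9 RPKM. Also among the 12 genes with the largest rise were IFI44, IFIT1, OAS1, IFIT2, IFI44L, ASMTL and the actin-like gene ACTL8. ASMTL rose from 7.49 ± 0.14 to 102 ± 7.61 RPKM, and the strand setting of the counting is not known for this gene, which has an antisense partner. TMPRSS11E, a transmembrane serine protease gene, was listed at 0 in both uninduced libraries and at 10.99 and 5.67 RPKM in the induced ones. The limma adjusted p of these 12 genes was at most 0.000123.

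The largest fall was that of CYP24A1, which encodes the vitamin D 24-hydroxylase, from 56.9 ± 6.95 to 9.03 ± 2.54 RPKM (log2 change -2.55 ± 0.16 SE). The other genes among the 12 largest falls were UBA2 and 10 replication-dependent histone genes. HIST1H2BL fell from 93.5 ± 12.2 to 20.6 ± 5.90 RPKM, HIST1H2AB from 389 ± 18.9 to 97.4 ± 6.28 RPKM and HIST1H3B from 950 ± 69.3 to 284 ± 37.9 RPKM. Histone genes of this cluster are nearly identical in sequence, and the counting could have split their reads, so single members are uncertain. In all, limma called 1578 genes higher and 3411 genes lower with induction, 46.2% of the genes tested. All 4989 moved the same way in both lines, which follows in large part from the test. A gene with opposite changes in the lines varies within groups by as much as it changes, so it is hardly called. Of the called genes, 190 were higher and 167 lower by at least 2-fold. The excess of lower genes depended on scale, since 68.4% of calls were lower as deposited, 50.1% after median-of-ratios scaling (2258 higher, 2263 lower) and 52.3% after quantile normalization (2100 higher, 2300 lower). The median log2 change of all genes was -0.092 as deposited, 0.0012 after median-of-ratios scaling and -0.015 after quantile normalization, and list medians shift with it. Without minus replicate 2 the higher genes numbered 1015, and without minus replicate 1 the lower genes numbered 2258.

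Interferon-stimulated genes formed the list with the largest median change. All 34 tested members of 40 listed rose, over all genes and adjusted over the list alone. Their median log2 change was 2.02, or 2.07 in line 1 and 1.91 in line 2. The smallest row maximum in the deposited values was 3.00 RPKM. A member that stayed low in every library would therefore be missing from these counts. IFI44 rose from 2.51 ± 0.32 to 54.0 ± 3.01 RPKM, IFIT1, an antiviral RNA-binding protein gene that shares sequence with IFIT1B, from 9.69 ± 1.23 to 125 ± 2.49 RPKM, and OASL from 9.09 ± 0.76 to 71.0 ± 4.93 RPKM. The camera adjusted p was 1.4e-34 with the preset correlation, and adjusted p = 0.303 with an estimated correlation. With an estimated correlation camera called 0 lists, in a fit with 2 residual degrees of freedom (lowest adjusted p = 0.249, 4 lists at an unadjusted p under 0.05). None of the 15 calls with the preset correlation held, whereas 13 of the 15 were called by fry. Fry did not call the ribosomal protein list (fry adjusted p = 0.119) or the ATF4-linked stress list (fry adjusted p = 0.138). It did call nuclear oxidative phosphorylation genes (fry adjusted p = 0.0048) and snoRNA host genes (fry adjusted p = 0.030), which camera did not call.

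Targets of p53 rose as well. All 29 tested members were higher, also adjusted over the list alone, with a median log2 change of 0.74 (camera adjusted p = 6.9e-21, adjusted p = 0.249 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 99.8 ± 0.19 to 216 ± 11.3 RPKM, BTG2 from 13.6 ± 0.77 to 34.3 ± 0.76 RPKM, and the apoptosis gene BBC3 from 7.18 ± 0.10 to 17.1 ± 1.04 RPKM.

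Genes of the cell cycle fell. All 31 mitotic genes were lower, also adjusted over the list alone, with a median log2 change of -1.01 (camera adjusted p = 6.0e-17, adjusted p = 0.303 with an estimated correlation). CCNA2 fell from 64.2 ± 0.75 to 27.0 ± 0.62 RPKM and BIRC5 from 81.0 ± 2.55 to 34.6 ± 0.45 RPKM. All 29 genes of DNA replication were lower, also adjusted over the list alone, with a median of -0.95 (camera adjusted p = 3.9e-15, adjusted p = 0.249 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell from 89.6 ± 0.08 to 39.4 ± 0.02 RPKM and UHRF1 from 47.3 ± 0.41 to 21.0 ± 0.13 RPKM. All 28 tested replication-dependent histone genes were lower, also adjusted over the list alone, with a median of -1.42 (camera adjusted p = 3.0e-16, adjusted p = 0.352 with an estimated correlation).

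Genes of cholesterol synthesis fell in 21 of 23 members, and in 23 of 23 adjusted over the list alone, with a median log2 change of -0.80 (camera adjusted p = 3.9e-08, adjusted p = 0.471 with an estimated correlation). INSIG1, a sterol-responsive regulator of the pathway, fell from 32.9 ± 2.99 to 9.59 ± 0.65 RPKM and LSS, lanosterol synthase, from 18.7 ± 1.51 to 8.84 ± 0.28 RPKM. Heat shock genes were lower in 10 of 14 and higher in 1, or lower in 12 and higher in 1 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 0.0015, adjusted p = 0.352 with an estimated correlation). HSP90AA1 fell from 548 ± 19.1 to 324 ± 2.96 RPKM. Proteasome genes were lower in 27 of 31, or 28 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 5.2e-07, adjusted p = 0.492 with an estimated correlation), including PSMB6 from 179 ± 2.41 to 121 ± 8.13 RPKM. The proteasome median was -0.23 after quantile normalization. Mitochondrial ribosome genes were lower in 26 of 32, or 28 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 3.2e-06, adjusted p = 0.249 with an estimated correlation), including MRPL11 from 54.7 ± 1.36 to 29.5 ± 0.77 RPKM.

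Lysosome and autophagy genes were higher in 14 of 22 and lower in 1, or higher in 15 and lower in 1 adjusted over the list alone, with a median log2 change of 0.37 (camera adjusted p = 9.3e-07, adjusted p = 0.352 with an estimated correlation). CTSB, the lysosomal protease cathepsin B, rose from 46.8 ± 2.42 to 206 ± 2.04 RPKM. Epithelial genes were higher in 9 of 18, and in 9 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 5.1e-05, adjusted p = 0.270 with an estimated correlation). ST14, the membrane protease matriptase, rose from 48.7 ± 1.88 to 177 ± 21.6 RPKM and CDH1, E-cadherin, from 13.4 ± 0.98 to 19.1 ± 0.42 RPKM. ATF4-linked stress genes were higher in 8 of 29 and lower in 2, or higher in 8 and lower in 1 adjusted over the list alone, with a median of 0.081 (camera adjusted p = 0.001, adjusted p = 0.548 with an estimated correlation). The ATF4 list's median was 0.16 without plus replicate 1, 0.025 without plus replicate 2, 0.18 after median-of-ratios scaling and 0.21 after quantile normalization. ATF3 rose from 6.53 ± 0.19 to 18.3 ± 3.00 RPKM and DDIT3 from 13.8 ± 0.70 to 26.2 ± 2.03 RPKM. Immediate early genes were higher in 6 of 18 and lower in 1, with the same counts adjusted over the list alone, and a median of 0.082 (camera adjusted p = 0.012, adjusted p = 0.303 with an estimated correlation). That list's median was 0.13 without plus replicate 1, 0.18 after median-of-ratios scaling and 0.15 after quantile normalization. Its camera adjusted p was 0.073 without plus replicate 2, and 0.0034 to 0.303 over all alternatives. JUN rose from 5.79 ± 0.45 to 11.6 ± 1.79 RPKM. Ribosomal protein genes were higher in 10 of 55, or in 3 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 3.3e-06, adjusted p = 0.563 with an estimated correlation). The ribosomal protein median was 0.052 without plus replicate 2, 0.22 after median-of-ratios scaling and 0.17 after quantile normalization. RPL31, whose reads are uncertain because ribosomal protein genes have many pseudogene copies, was at 352 ± 4.98 and 436 ± 14.8 RPKM, and its adjusted p of 0.0069 in limma became 0.066 without minus replicate 1 (0.00088 to 0.066 over all alternatives).

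**Figure D2:**
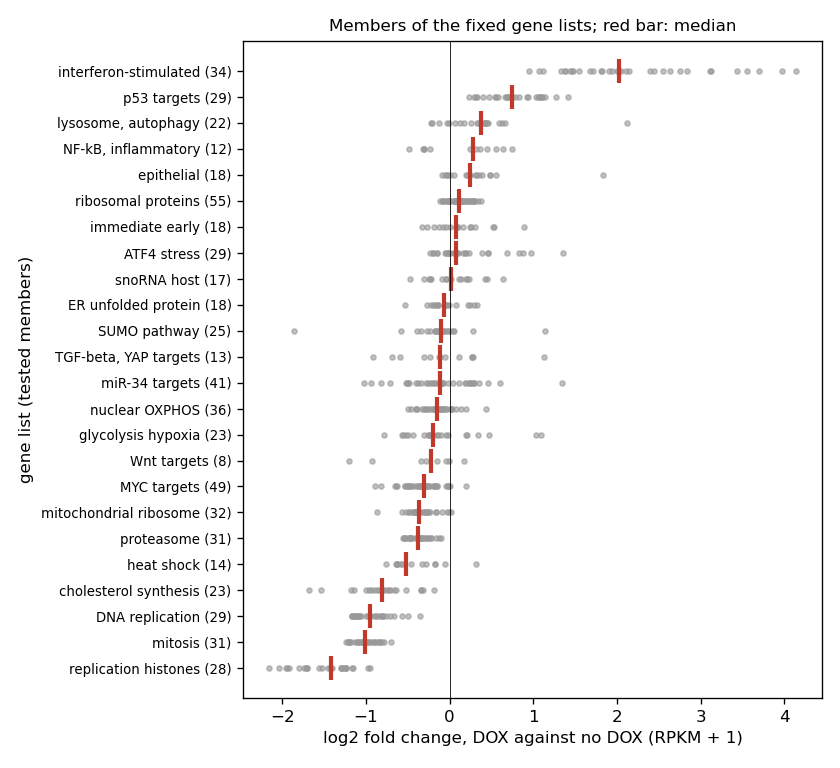
Log2 fold change of each tested member (grey points) of the 24 tested lists, with the list median as a red bar and the number of members in parentheses. The medians run from -1.42 for replication histones to 2.02 for interferon-stimulated genes.

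The series title names the genes targeted by miR-34b/c. Of 41 tested published targets of the miR-34 family, 8 were higher, 15 were lower and 18 were not called, with the same counts of calls adjusted over the list alone. Their median log2 change was -0.12 as deposited, -0.020 after median-of-ratios scaling and -0.0020 after quantile normalization, and camera did not call the list (camera adjusted p = 0.757, adjusted p = 0.943 with an estimated correlation). GMNN, which restrains replication licensing, fell from 36.7 ± 2.39 to 17.5 ± 0.39 RPKM and CDC25A from 16.7 ± 1.25 to 8.19 ± 0.52 RPKM, while the transcription factor gene KLF4 rose from 2.12 ± 0.04 to 6.89 ± 0.04 RPKM. Genes with a miR-34a/c seed site in the 3' UTR (1582 of 9709 searched) had a median log2 change of -0.076 against -0.10 for genes without one, and those with a miR-34b site (1502) had the same median of -0.076 against -0.10. The difference was 0.028 for the miR-34a/c site, 0.049 without minus replicate 1 and 0.017 without minus replicate 2, and 0.027 for the miR-34b site, 0.016 after quantile normalization. Neither set was called (camera adjusted p = 0.262 for both, adjusted p = 0.774 with an estimated correlation). Of 100 shuffled sites, 39 gave a difference as low as that of the miR-34a/c site and 61 as low as that of the miR-34b site. The 8 listed genes at the miR-34 loci are not analysed here.

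MYC, a published miR-34 target, was at 105 ± 0.47 RPKM without and 97.2 ± 18.4 RPKM with induction, a log2 change of -0.12 ± 0.11 (SE, limma adjusted p = 0.427). It went from 105 to 84.2 RPKM in line 1 and from 104 to 110 RPKM in line 2. Without plus replicate 2 its log2 change was -0.31 (adjusted p = 0.00092), and without plus replicate 1 it was 0.074 (limma adjusted p = 0.344), and over all alternatives the adjusted p was 0.00092 to 0.919. Targets of MYC in ribosome biogenesis and metabolism were lower in 39 of 49, or lower in 42 and higher in 1 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 3.6e-07, adjusted p = 0.303 with an estimated correlation). This median was -0.18 after quantile normalization. UNG fell from 56.0 ± 2.02 to 29.8 ± 1.15 RPKM and FBL, fibrillarin, from 76.4 ± 4.21 to 49.2 ± 0.92 RPKM.

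The other lists were not called by camera. SUMO pathway genes, UBA2 included, were lower in 7 of 25 and higher in 2 (lower in 6 and higher in 2 adjusted over the list alone, camera adjusted p = 0.398, adjusted p = 0.681 with an estimated correlation). SAE1, the partner of UBA2 in the E1 enzyme, fell from 98.8 ± 1.48 to 75.3 ± 2.76 RPKM, and SP100, a nuclear body gene, rose from 7.26 ± 0.03 to 17.2 ± 0.20 RPKM. Nuclear oxidative phosphorylation genes were lower in 14 of 36 and higher in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.102, adjusted p = 0.352 with an estimated correlation). NF-kB and inflammatory genes were higher in 5 and lower in 4 of 12, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.115, adjusted p = 0.504 with an estimated correlation). Host genes of snoRNAs were higher in 6 and lower in 4 of 17, with the same counts adjusted over the list alone (camera adjusted p = 0.102, adjusted p = 0.352 with an estimated correlation), and GAS5 rose from 171 ± 1.09 to 266 ± 2.57 RPKM. That list was called after quantile normalization (adjusted p = 0.022) and with a mean of at least 5 RPKM (adjusted p = 0.0497), with 0.022 to 0.352 over all alternatives. Wnt targets were lower in 3 of 8, with the same count adjusted over the list alone (camera adjusted p = 0.288, adjusted p = 0.703 with an estimated correlation), and DKK1, a secreted Wnt inhibitor, fell from 220 ± 6.73 to 95.1 ± 0.97 RPKM. Glycolysis and hypoxia genes were higher in 4 and lower in 9 of 23, or 5 and 9 adjusted over the list alone (camera adjusted p = 0.697, adjusted p = 0.927 with an estimated correlation), and the glucose transporter gene SLC2A1 rose from 28.2 ± 2.48 to 59.0 ± 5.11 RPKM. For unfolded protein response genes (3 higher and 4 lower of 18, camera adjusted p = 0.951) and TGF-beta and YAP targets (2 higher and 4 lower of 13, camera adjusted p = 0.964), the medians of -0.061 and -0.11 and the means of -0.050 and -0.076 were below 0 while camera's direction was up. The unfolded protein median lay above 0 after median-of-ratios scaling (0.041) and quantile normalization (0.048), and was -0.14 without plus replicate 1 and -0.025 without plus replicate 2. The TGF-beta and YAP median was -0.019 and -0.030 under these scalings. The adjusted p was 0.966 for both with an estimated correlation. Both kept these counts adjusted over the list alone.

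Lists with fewer than 5 tested members were not tested as lists. Of 2 mesenchymal genes, ACTA2 rose from 2.08 ± 0.60 to 4.56 ± 0.66 RPKM. Of 3 intestinal differentiation genes, CA2 fell from 26.4 ± 3.02 to 17.9 ± 4.91 RPKM and DPP4 from 2.94 ± 0.66 to 1.42 ± 0.32 RPKM, and without minus replicate 2 the limma adjusted p was 0.097 for CA2 and 0.093 for DPP4. The log2 change of CA2 was -0.56, and -0.29 without plus replicate 1. For CA2 the adjusted p was also 0.075 after median-of-ratios scaling and 0.107 after quantile normalization. Of 4 germline genes, MAGEB2 fell from 126 ± 2.33 to 111 ± 0.74 RPKM, with a limma adjusted p of 0.12 without minus replicate 1, 0.192 without minus replicate 2, 0.27 after median-of-ratios scaling, 0.207 after quantile normalization and 0.053 with no variance trend. MAGEA3 and MAGEA6, which share sequence and were not called, had a limma adjusted p of 0.0043 and 0.013 without plus replicate 1. Leukocyte and endothelial markers and mitochondrially encoded genes are not analysed here.

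The design uses 2 independent shRNAs to set aside effects of either one. At least 2-fold rises were seen in 198 genes in line 1 and 180 in line 2, with 145 in both, where independent lists would share 3.30. At least 2-fold falls were seen in 198 and 174 genes, with 131 in both, where independent lists would share 3.19. Doxycycline was given in both lines, so an overlap above these counts does not separate a response to it from UBA2 loss. A single gene, for a small RNA, changed 2-fold in opposite directions. The fold changes of the lines correlated across genes with a Pearson r of 0.886 and a Spearman rho of 0.836, and genes are not independent replicates. Comparing the lines with each other, limma called 0 genes, with 30 at an unadjusted p under 0.05. That fit leaves the change with induction in the residual spread, so it could hardly call a line difference. With the group as a block limma called 0, with 742 at an unadjusted p under 0.05. Whether the response itself differed between lines was not tested, since no residual degrees of freedom remain.

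**Figure D3:**
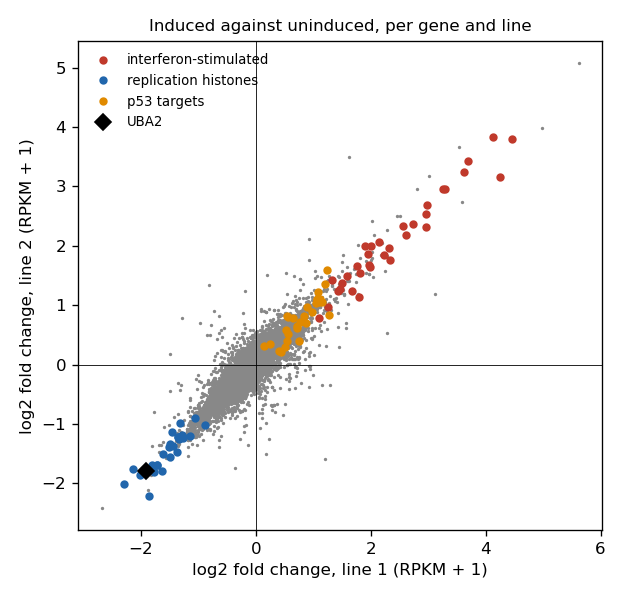
Log2 fold change with induction in line 1 (x axis) against line 2 (y axis) for 10797 genes, with interferon-stimulated genes in red, p53 targets in orange, replication histones in blue and UBA2 as a black diamond. The coloured genes lie along the diagonal, and r across genes was 0.886.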

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

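The scaling test and the test of replication-independent histones below were set before their results were seen. The tests of transcript length, GC content, a single shRNA, shared reads, the doxycycline response, short transcripts, an equal loss of histone transcripts and S phase were chosen after the result was seen. A first test of length and GC content, set before the result was seen, which removed the slope but kept the overall median, was dropped because the kept median fixed its outcome.

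MYC and CDX2 moved in opposite directions in the lines, which is why they are given here, and the difference was not tested. The log2 change of MYC was -0.31 in line 1 and 0.078 in line 2, a difference of -0.39. That of CDX2 was 0.025 in line 1 and -0.18 in line 2, a difference of 0.21.

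More genes were called lower than higher. The scale of the deposited RPKM cannot be told apart from a true excess: after median-of-ratios scaling 50.1% of calls were lower, but that scaling centres the fold changes, so an even split follows from it in large part. Transcript length and GC content were taken for 9760 genes with a protein-coding transcript in GENCODE 29, 90.4% of all genes. Genes without one were left out. For the 9760 genes, a length trend is argued against as the source of the whole excess. At least 60.1% of them were below 0 in each of 5 equal groups by transcript length. A trend was present, since the share fell from 67.8% in the shortest group to 60.1% in the longest. The same holds for GC content, with 70.3% in the group of lowest GC content and at least 58.9% in each group. A partial contribution of either was not tested. No biological explanation of the excess was tested.

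Interferon-stimulated genes were higher. An effect of a single shRNA sequence is argued against only if the induced libraries carry different shRNAs, since the smaller of the line medians was 1.91. That condition rests on the elimination described above, because the label of an induced library gives no shRNA number. The calls of the members add little to this, since a call already favours genes that moved the same way in both lines. Reads shared between listed members of a symbol family are argued against as the source of the whole rise. The 8 members with no other member of their symbol family in the list had a median log2 change of 1.90. Families were judged by symbol and not by sequence, so reads shared with genes outside the list were not tested. A response to doxycycline or to any induced shRNA cannot be told apart from a response to UBA2 loss, because the design analysed here has 0 libraries with doxycycline and no shRNA or with a non-targeting shRNA. A response to UBA2 loss remains a hypothesis.

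Replication-dependent histones were lower. A general loss of transcripts up to 1537 nt, the 90th percentile of the histone transcripts, is argued against. The 1224 other protein-coding genes up to that length had a median log2 change of -0.14 (quartiles -0.33 and 0.063). Most histone transcripts were shorter than this limit, and a loss confined to shorter transcripts was not tested. An equal loss of all histone transcripts is argued against, since the median of 8 replication-independent histone genes lay 1.10 above that of the replication-dependent genes, with SDs of 0.40 and 0.32 among members. A smaller general loss is not decided, since that median was -0.32, between the bounds of -0.7 and -0.3 set beforehand. The median lay above these bounds after median-of-ratios scaling (-0.22) and quantile normalization (-0.17). The 8 members were also spread, from -0.79 to 0.40, with 5 called lower and 0 higher. A lower share of cells in S phase is consistent with the S phase list, whose median was -0.95, and may contribute, but the share of cells in each phase was not measured here.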

How the results depend on the processing

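The alternative in which genes with identical values were counted once was chosen after seeing the data, and gave 1573 higher and 3404 lower genes. The fall of UBA2 kept its call under every alternative run, with a log2 change between -1.997 and -1.52. The minimums of 0.1 RPKM and none removed no gene and test nothing. Genes called lower numbered 2263 after median-of-ratios scaling, which centres the fold changes. Leaving out 1 library gave 1015 to 1556 higher and 2258 to 3341 lower genes, with fewer samples in the fit and the lone library assumed to vary like the other group's. With the replicate block, limma called 1647 higher and 3508 lower genes, and among the genes named by the rule and the fixed lists the block changed no other call. The count of 15 lists called by camera fell to 0 with an estimated correlation and was 14 to 15 without 1 library. Genes changed in both lines numbered 139 with a pseudocount of 5, 981 at 1.5-fold and 66 at 3-fold, against 276. The correlation between lines was 0.873 and 0.908 with pseudocounts of 0.1 and 5, 0.911 with a mean of at least 5 RPKM and 0.920 without small RNA genes. The miR-34 results kept their sign and stayed uncalled under every alternative run, but the median of the target list ranged from -0.14 to -0.0020, nearest 0 under the scalings.

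After quantile normalization 3814 of the 4989 called genes kept their call and 14 did not keep their sign, a change of 0 included. After median-of-ratios scaling 3841 kept their call and 0 lost their sign. Among the named genes and fixed lists, the values that reversed were not called, and the cause was not tested. After median-of-ratios scaling CDX2 was 0.0052, MAGEA12 0.055 and the unfolded protein list 0.041. After quantile normalization MYC was 0.019, MAGEA6 0.013 and the unfolded protein list 0.048. With a mean of at least 5 RPKM, and fewer genes, the NF-kB list was -0.27. Without 1 library MYC ranged from -0.31 to 0.074, MAGEA12 from -0.083 to 0.024 and S100A4 from -0.0065 to 0.12, with reversed values of 0.017 for MAGEA12 and -0.0029 for S100A4 without minus replicate 1. Of 1729 values of called named genes, 1705 kept their call, 24 lost it and 0 reversed. Among named genes that were not called, 6 values gained a call. They were those of EPHB2 without small RNA genes (limma adjusted p = 0.040), without minus replicate 2 (0.019) and without plus replicate 2 (0.035), MAGEA3 (0.0043) and MAGEA6 (0.013) without plus replicate 1, and MYC without plus replicate 2 (0.00092). Depth is unknown, so its limits are not given.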

Other observations

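The gene groups here were chosen after their values were seen, so their counts describe these libraries and are no independent evidence. Of 17 genes of antigen presentation, 14 rose and none fell (0), with a median log2 change of 0.99. HLA-B rose from 108 ± 1.91 to 404 ± 40.7 RPKM (SD, n = 2). It shares sequence with related genes, and the assignment of its reads is uncertain. The interferon lambda gene IL28B was at 0.10 ± 0.06 RPKM without and 2.66 ± 0.49 RPKM with induction. Its highest library, at 3.00 RPKM, lay at the smallest row maximum of the deposited values, so this is a gene of low level. Of 20 tubulin genes, 16 fell, with TUBA1B going from 1044 ± 40.0 to 575 ± 22.4 RPKM. Of 35 HNRNP and SRSF genes, which encode RNA-binding and splicing proteins, 30 fell and 1 rose, and HNRNPM went from 73.0 ± 0.36 to 44.6 ± 1.42 RPKM. Of 10 genes of the CCT chaperonin, 9 fell. These directions of the medians were kept under median-of-ratios scaling and quantile normalization.

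Of 93 H/ACA small nucleolar RNA genes, 52 rose and 2 fell, with a median of 0.65 in line 1 and 0.22 in line 2. Of 134 C/D small nucleolar RNA genes, 28 rose and 19 fell, with a median of 0.0094, and of 24 Cajal body RNA genes 15 rose and 0 fell, with a median of 0.40. Of 146 microRNA genes, 18 rose and 41 fell, with a median of -0.15. These RPKM values are per gene symbol, so mature microRNAs were not measured apart from precursor or host transcript reads. Among all 10797 genes 1578 were called higher and 3411 lower, and camera did not set the microRNA genes apart (camera adjusted p = 0.864). Of 249 zinc finger genes, 61 rose and 28 fell, with a median of 0.036. After median-of-ratios scaling and quantile normalization the medians were 0.10 and 0.092 for C/D RNAs, 0.50 and 0.55 for Cajal body RNAs, -0.058 and -0.10 for microRNAs and 0.12 and 0.088 for zinc finger genes. Of 22 SNAR genes, 20 rose, and their median of 1.07 became 0 after quantile normalization. The 14 SNAR-A genes hold 3 distinct sets of values, so single members are uncertain. ASMTL-AS1 was at 0.62 ± 0.21 and 6.48 ± 0.44 RPKM, rising with ASMTL. The 10 genes with the highest RPKM in each library held 22.4% and 23.0% of the summed RPKM without induction and 29.1% and 27.8% with it.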
